A study of Gallus gallus with 13 samples.

How the data were processed

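The data were Repli-seq profiles of DT40 chicken cells, with 1 library for each of 4 S-phase fractions in Wt and in the modified clone. Per the labels' protocols, growing cells were labelled with BrdU for 1 h and sorted into fractions by flow cytometry. Nascent strands were pulled down with an antibody against BrdU and passed through whole-genome amplification before library construction, so unequal amplification can be part of the measured signal, which was not tested. Reads were aligned to galGal5 with Bowtie2, per the submitters' processing notes. The version of Bowtie2, the filters, the normalization and the smoothing are not given in the sources used here.

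The values the authors deposited are scores, in SD units, at positions spaced 1 kb. The fraction profiles are normalized, per the file headers, and their values have mean 0 and SD 1 over each chromosome. They cover chromosome 1 in both lines (8 profiles) and chromosome 14 in Wt (4 profiles). The headers of the 2 weighted-average timing profiles name the lines Wt and cl6, and cl6 was taken here to be the modified clone. These profiles, named weighted averages per the file headers, cover chromosome 1 and have mean 0 and SD 1 within each of 16 contiguous stretches. Values of different stretches are therefore not on a common scale, and a short stretch or its ends can carry large values. The ranks fixed before the data were examined pool windows of all stretches, so ranks within the stretch of the target region are given beside them. The weights are not given in the sources used here. A least-squares fit of the Wt weighted average on the 4 fractions, in the stretch that holds the target region, gave coefficients of 0.814, 0.682, 0.422 and 0.0703 for S1 to S4, with a coefficient of determination of 0.90. Higher values were thus earlier, and the value also rose with the total signal of a locus. Across 50 kb windows in Wt its Pearson r with the summed signal was 0.799, against 0.384 for the share-based index. Counts are not part of these profiles, so depth is unknown and no counting interval was computed.

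The share-based index was computed from the fraction profiles. Each fraction was set to 0 at its 1st percentile, values below that were set to 0, and the result was scaled to equal means. The fractions were weighted 4, 3, 2 and 1 from S1 to S4 and divided by their sum, so that total signal cancels. For differences in SD units the index was centred and scaled within the same 16 stretches. The fraction with the highest scaled signal was taken in windows of 50 kb. On chromosome 14 the last 546 positions (3.51%) were left out, since they held extreme values that made up 99.98% of the S1 variance and set the scale of the whole profile.

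All differences are clone minus Wt. Means were taken over the target region and over 100 kb centred on the labelled insertion positions, and were ranked among windows of the same length moved in steps of 50 kb over chromosome 1 outside the target region. Ranks count windows with as high a difference, unless both directions are named. At least 50% of the positions of a window had to hold a value. With 1 library per group no test was possible, windows are not replicates, and no p-value was computed. A value under another setting was called moved when it changed by more than the SD of the other windows, by more than 1.5-fold for counts and lengths, by more than the SD over stretches for the correlation, or outside an exact (Clopper-Pearson) 95% interval for the percentages of windows.

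The regions named were fixed before the data were examined. They are the target region, the insertion positions, and outside the target region the 5 runs towards earlier and the 5 towards later replication with the largest summed difference, formed by the top 1% of windows and merged across gaps of 1 window. Genes were to be named only with galGal5 coordinates. Regions named by another choice are said to have been chosen after the data had been seen.

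The statistics were tested on simulated data in which the clone's differences were moved along the chromosome and a shift was added at 20 mid-replicating places, 1 at a time, over 201 kb and 193978 positions. For an added weighted-average shift of 0.86, which a window mean returns by construction, 14 of the 20 places ranked above the 99th percentile. The rule for the extent recovered a median of 25 kb at the 99th percentile and 150 kb at the 95th, so it understates length. For a change added to the fractions, 8 of the 20 places ranked above the 99th percentile of the share-based index and 15 above the 95th, against 2 above the 95th before the change was added. Both added changes were sized close to the differences found at the insertion positions.

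The alternatives tried were the share-based index in place of the weighted average, that index without each fraction in turn, quantile normalization and median centring of the clone to Wt, reference windows of similar Wt timing, other window sizes and widths, the 95th percentile, shares of the summed signal, and leaving out the lowest 5% of positions by summed signal. Reference windows over 500 kb from a stretch end, reference windows of the stretch that holds the target region, and other window sizes or unscaled values for the leading fraction, were added after seeing the data.

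The asynchronous library and the 4 Hi-C libraries were not analysed here. The gene annotation at hand belongs to another build, GRCg7b, and coordinates were not converted. The timing of the 12 gene lists fixed beforehand and of the endogenous globin and actin loci was therefore not analysed here. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.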

Results

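Replication timing was compared between wild-type (Wt) DT40 cells, a chicken B cell line from a bursal lymphoma, and a homozygous clone of the same line. Per the labels, the clone carried regulatory modules made of βA-globin and β-actin elements in a part of chromosome 1 that normally replicates in mid to late S phase. The design asked whether that region came to replicate at another time of S phase. In Repli-seq, cells are pulsed with the nucleotide analog BrdU, sorted by DNA content, and the BrdU-labelled nascent strands are sequenced, so that a locus gives most signal in the fraction in which it replicates. The pulse lasted 1 h and the 4 sorted fractions ran from S1, the earliest, to S4, the latest. Each fraction was represented by 1 library per line, 8 libraries in all. With no replicate library, no difference below has a replicate error or a p-value. The ranks among windows describe these libraries only, and the read depth is unknown because the profiles hold no counts. Of the 13 samples, 5 were not analysed here, namely the asynchronous Wt library and the 4 Hi-C libraries.

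The target region, at position 71981290 to 73532377 of chromosome 1 (galGal5), had a higher weighted-average timing value in the clone than in Wt, and higher is earlier. Its mean was 0.433 SD units in Wt and 0.649 in the clone, a difference of 0.216. Among 3831 windows of the same length elsewhere on the chromosome, 67 had a difference as high, and the SD of these windows was 0.0969. A share-based index, in which the total signal of a locus cancels, gave a difference of 0.114 SD units, which 255 of the 3831 windows reached (93.3rd percentile; 390 windows without S1 and 540 without S4), and on its unscaled range from 1 to 4 a difference of 0.0839 at the 98.9th percentile. Within the stretch of chromosome 1 that was scaled together with the target region, a comparison added after the data had been seen, 21 of 485 windows were as high in the weighted average and 3 of 485 in the index in SD units. Windows moved in 50 kb steps overlap heavily. About 125 windows of this length fit on chromosome 1 without overlap, and fewer in that stretch, so the windows as high may come from few loci. The regional mean also pools parts that differed in opposite directions. In the weighted average it includes a rise of 1.08 at 72950001 to 73050000, where the index differed by 0.0433 SD units. It also includes a difference of -0.434 at 72200001 to 72300000.

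At the insertion positions the difference was larger. The labels place the modules of the Hi-C lines at positions 72565520 and 72536060, with a reporter at 72548589, and the 100 kb centred on them ran from 72500790 to 72600789. There the weighted average was -0.0333 in Wt and 0.824 in the clone, a difference of 0.858, and 18 of 3845 other windows of 100 kb were as high. The share-based index, on a scale from 1 (all signal in S4) to 4 (all signal in S1), was 2.25 in Wt and 2.70 in the clone. In SD units this was a difference of 0.625, which 34 of the 3845 windows reached, and 152 when S4 was left out of the index. Within the same stretch, 3 of 535 windows were as high in the weighted average and 0 of 535 in the index. Counted in either direction over the chromosome, 28 of 3845 windows differed as much in the weighted average and 108 in the index, and for the target region 110 and 591 of 3831. The insertion positions of the Repli-seq clone itself are not given in the sources used here, and no gene was placed in the region, since the annotation at hand belongs to another build.

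At the insertion positions the clone had more nascent-strand signal in S1 and S2 and less in S4, with the largest difference of the deposited values in S2. The S2 signal was 0.325 SD units in Wt and 1.35 in the clone, a difference of 1.02 that 10 of 3845 windows reached. The S1 signal was -0.538 in Wt and -0.0491 in the clone, a difference of 0.488 at the 98.2nd percentile. The S4 signal was 0.0137 in Wt and -0.719 in the clone, a difference of -0.732 at the 0.858th percentile. The S3 signal was 0.837 in Wt and 0.726 in the clone, and this difference of -0.111 lay well inside the spread of other windows, whose SD was 0.242. As shares of the summed signal, S2 took 29.3% in Wt and 42.8% in the clone, S1 9.05% and 17.8%, S3 38.8% and 30.8%, and S4 22.9% and 8.61%. By share the largest difference was in S4, at -14.2 percentage points, against 13.6 in S2. The difference in S3 was thus larger as a share than as a deposited value, and the summed signal was 18.2% higher in the clone. Over the whole target region the deposited values kept the same order at a smaller scale, with differences of 0.189 in S2, 0.133 in S1, -0.0115 in S3 and -0.155 in S4.

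**Figure D1:**
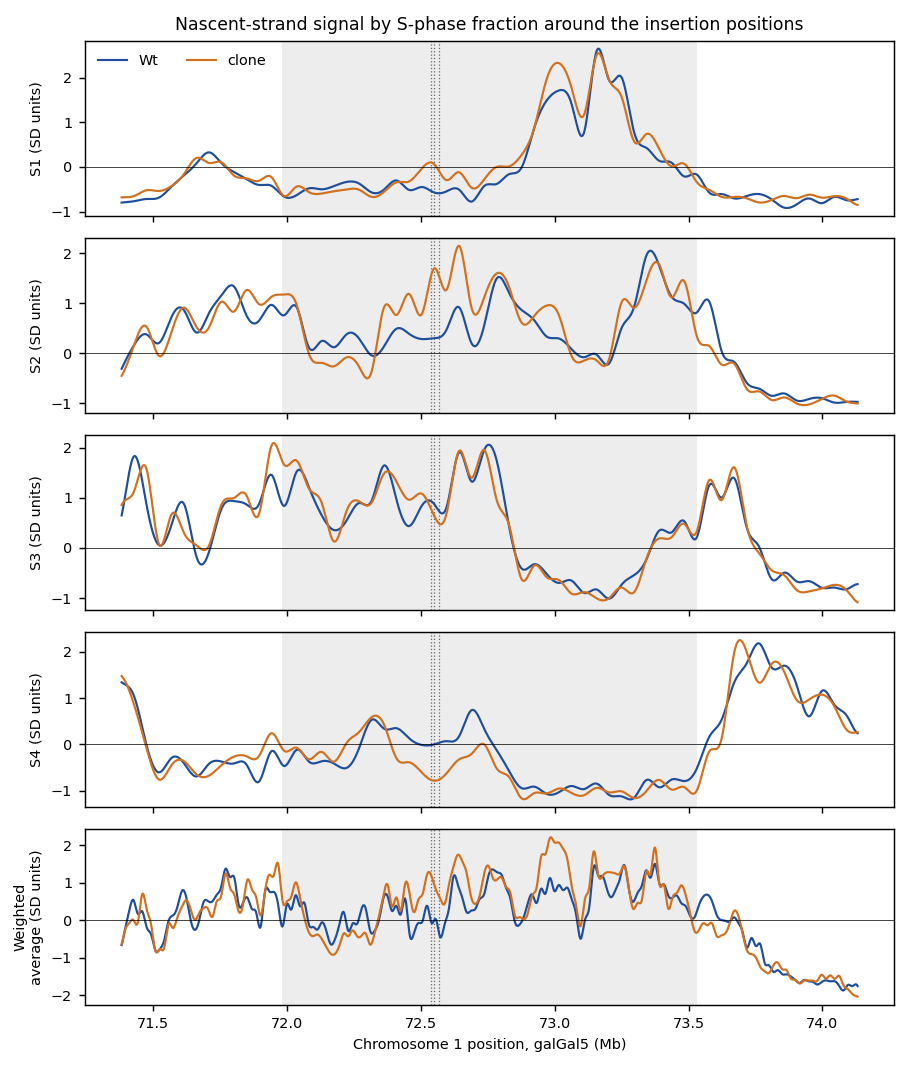
Nascent-strand signal in S1 to S4 and the weighted-average timing value, in SD units, against position on chromosome 1 (Mb) in Wt (blue) and the clone (orange), 1 library per fraction and line. The target region is shaded and dotted lines mark the labelled insertion positions, where S2 was 1.02 higher and S4 -0.732 relative to Wt as means over 100 kb.

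The fraction with the highest signal also differed around the insertion positions. In Wt, S3 led without a break from 71850001 to 72800000, a run of 950 kb and the longest of the 194 runs led by S3 on chromosome 1. In the clone this run was split. S2 led from 72450001 to 72650000, which is 200 kb around the insertion positions, and S3 kept the lead over 550 kb upstream and 100 kb downstream of it. At both ends of the Wt run S2 led in the clone as well, up to 71900000 and from 72750001. The 200 kb was 140 kb with windows of 20 kb and 150 kb with unscaled values. The neighbouring stretch from 72900001 to 73300000 was led by S1 in both lines. This measure was chosen after the data had been seen, and with windows of 100 kb another run led by S3 in Wt was longer, at 1000 kb.

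The differences around the insertion positions did not span the whole target region. Within 500 kb, the largest S2 difference, 1.40, lay at position 72551481, 0.691 kb from the centre of the insertion positions. The largest S4 difference, -0.949, lay 136.7 kb downstream of that centre, and the largest difference in the weighted average, 1.30, lay 447.7 kb downstream. In the share-based index the largest difference, 0.754 SD units, lay 1.691 kb from that centre. Around that centre the clone stayed above Wt over 517 kb in S2, over 497 kb in S1, over 428 kb in the weighted average and over 650 kb in the index. It stayed below Wt over 596 kb in S4 and over 103 kb in S3. The stricter rule set before the data were examined, contiguous 50 kb windows beyond the 99th percentile of absolute differences elsewhere, gave an interval of 50 kb, from 72525790 to 72575789. Only the central window passed, so 50 kb is the window size and not a measured extent. The length from this rule depended on the settings, with 0 kb for windows of 10 kb or 20 kb and 100 kb for the 95th percentile, and the rule returned a median of 25 kb for simulated shifts 201 kb long.

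The shift did not have the same sign across the whole target region. From 72200001 to 72300000 the weighted average was 0.0443 in Wt and -0.39 in the clone, with S2 at 0.297 and -0.218. This difference in the weighted average, -0.434, lay at the 4.94th percentile of other windows. From 72950001 to 73050000, inside the stretch led by S1, the weighted average was 0.866 in Wt and 1.95 in the clone, a rise of 1.08 that 9 of 3845 windows reached. There the share-based index differed by 0.0433 SD units and the summed signal was 26.3% higher in the clone. Both intervals were chosen after the data had been seen.

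Elsewhere on chromosome 1, differences as large as that at the insertion positions were rare. Of 3849 windows of 50 kb outside the target region, 24 differed at least as much as the window at the insertion positions (1.01), 15 of them earlier and 9 later in the clone. Of these windows, 16 lay within 500 kb of an end of the stretches in which the weighted average was scaled. Away from those ends, 8 of 3522 windows were as large, and in the stretch of the target region 2 of 537. Because each stretch was scaled on its own, sizes compared across stretches, here and in the runs that follow, are not on a common scale. With the share-based index, 116 of the 3849 windows differed at least as much as the window at the insertion positions.

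The top 1% of windows, 39 in number, formed 18 runs towards earlier and 15 towards later replication in the clone. The run with the largest summed difference towards earlier replication lay at 194700001 to 194850000, where the weighted average was -0.263 in Wt and 1.79 in the clone. The share-based index there was 3.23 in Wt and 3.22 in the clone. The next ran from 195700001 to 195800000, with -1.09 and 0.509, followed by 194350001 to 194400000 with 1.31 and 3.82. The runs at 100400001 to 100550000 (-0.212 and 0.554) and 194200001 to 194250000 (3.50 and 5.997) came after these. Towards later replication, the run at 78150001 to 78200000 came first, with 0.991 in Wt and -1.16 in the clone. That at 48100001 to 48200000, with 1.06 and 0.0743, was 1904 kb from the nearest stretch end. The others lay at 100300001 to 100350000 (1.14 and -0.507), 194600001 to 194650000 (1.72 and 0.116) and 195550001 to 195600000 (1.40 and -0.119). Of these 10 runs, 8 lay within 500 kb of a stretch end, and in 8 the difference in the share-based index, in SD units, had the same sign as that in the weighted average. In 4 of these 8, however, the index differed by less than the SD of windows elsewhere, 0.265, and in the run at 100400001 the unscaled index was 1.96 in Wt and 1.78 in the clone, opposite to the weighted average.

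**Figure D2:**
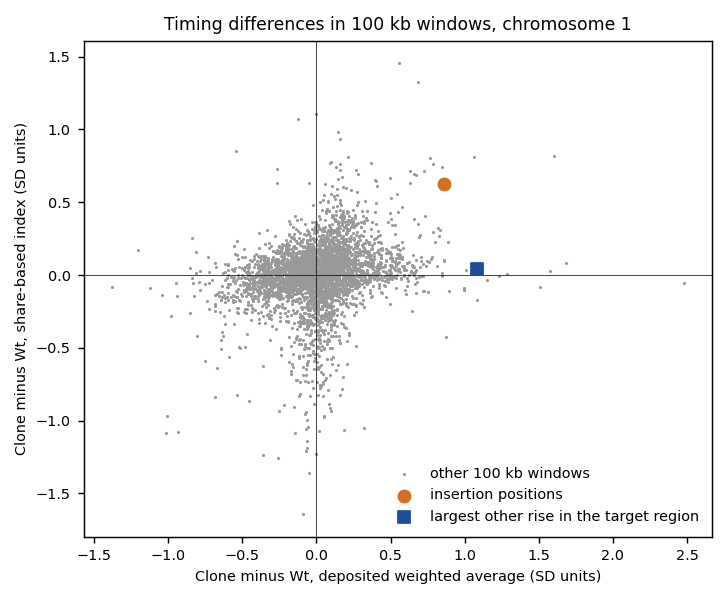
Clone minus Wt difference in the deposited weighted average (horizontal) and in the share-based index (vertical), both in SD units, for each 100 kb window of chromosome 1 outside the target region (grey). The insertion positions (orange circle) were high on both axes, at 0.858 and 0.625, whereas the largest other rise of the target region (blue square) was high on the horizontal axis alone, at 1.08 and 0.0433.

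Over most of chromosome 1 outside the target region the timing profiles of both lines were similar. Across 3849 windows of 50 kb outside the target region, the weighted averages of Wt and the clone had a Pearson r of 0.949 and a Spearman rho of 0.958. For single fractions, r was 0.959 in S1, 0.964 in S2, 0.954 in S3 and 0.932 in S4. Across positions within single stretches, r of the weighted averages ranged from 0.392 to 0.981. The lowest values were 0.392 and 0.407 in the stretches at the chromosome's ends (1670 and 572 positions), followed by 0.516 in a stretch of 950 positions and 0.708 in one of 1198. The median absolute difference of the weighted average was 0.162 SD units. Neighbouring windows are not independent, so these coefficients describe the profiles and carry no test.

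In Wt, the fraction that most often had the highest scaled signal was S4 on chromosome 1 and S1 on chromosome 14. On chromosome 1, S4 had the highest signal in 42.2% of 3881 windows of 50 kb, S1 in 22.4%, S2 in 17.8% and S3 in 17.6%. On chromosome 14, S1 led in 48.3% of 300 windows, S2 in 24.3%, S3 in 14.7% and S4 in 12.7%. The longest run led by S4 on chromosome 1 ran from 39900001 to 43100000 (3200 kb), and the longest led by S1 from 174350001 to 175500000 (1150 kb). On chromosome 14 the longest run led by S1 was 1750 kb, from 6000001 to 7750000, and the longest led by S4 was 1350 kb, from 10400001 to 11750000. These runs were chosen after the data had been seen. Each fraction was scaled to the same mean within a chromosome, so these shares rank windows within a chromosome. They cannot show whether chromosome 14 replicated earlier or later than chromosome 1.

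**Figure D3:**
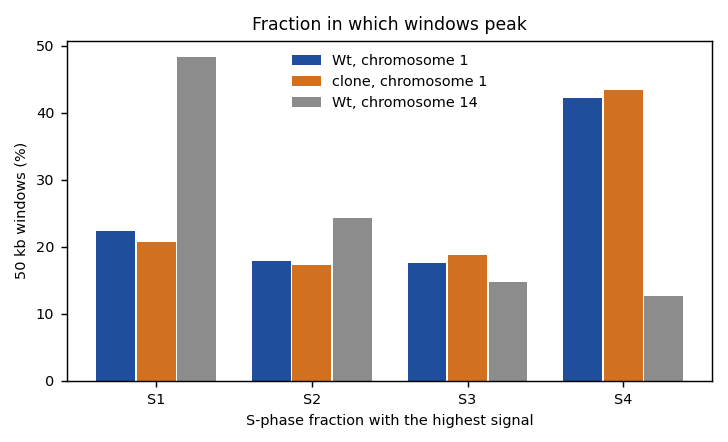
Percentage of 50 kb windows in which each S-phase fraction had the highest scaled signal, for chromosome 1 in Wt (blue) and the clone (orange) and chromosome 14 in Wt (grey), 1 library per fraction. S4 led in 42.2% of Wt windows on chromosome 1 and S1 in 48.3% on chromosome 14.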

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

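Of 76 alternative settings for 23 results, 61 left the value within the limits set for it, 15 moved it and 0 reversed it; 12 of the 76 were chosen after seeing the data. The shift of the target region, 0.216, was 0.114 with the share-based index (whichever reference windows were used), 0.0863 without S1 and 0.105 without S4, at the 89.8th and 85.9th percentile. The shift at the insertion positions, 0.858, was 0.55 with the index without S4, where 152 of 3845 windows were as high. The extent, 50 kb, was 0 kb with windows of 10 kb, 0 kb with 20 kb, 0 kb with the share-based index, and 100 kb with windows of 100 kb or the 95th percentile. At the 99th percentile, only the central window passed with windows of 50 kb and of 100 kb. With shares of the summed signal, S3 differed by -0.117 in the target region and -0.649 at the insertion positions. These values are on a rescaled range, where the SD of other windows was 0.0881 and 0.297, and are not percentage points. In percentage points the S3 share differed by -1.12 in the target region and -8.08 at the insertion positions. The 24 windows elsewhere as large as that at the insertion positions became 133 of 9623 with windows of 20 kb, 13 of 1924 with 100 kb, and 116 of 3849 with the share-based index. The limit for counts ignores the number of windows. With 100 kb the share of windows as large was close to that with 50 kb, so this move reflects fewer windows. With 20 kb the larger number of windows accounts for part of the rise, and the share was higher too. With the index the share was higher as well. The cause of the other changes was not tested. With reference windows away from the stretch ends, 7 of 3507 were as high as the weighted average at the insertion positions and 27 as high as the index. The gene list settings were not run for want of galGal5 coordinates, nor was the weighted average for chromosome 14, since the profiles used cover chromosome 1. No paired analysis was possible because each group held 1 library. Depth is unknown, so its effect on these values could not be assessed.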

Other observations

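All 5 tests in this part were chosen after the values they bear on had been seen. Along chromosome 1, the leading fraction was the same in Wt and the clone in 3451 of 3881 windows of 50 kb (88.9%). In the target region 5 of 32 windows were led by an earlier fraction in the clone and 0 by a later one. Outside it, 157 of 3849 windows (4.08%) were led by an earlier fraction and 268 by a later one. A change from S3 in Wt to S2 in the clone occurred in 40 windows, which formed 33 runs. The longest run, 4 windows from 72450001 to 72650000, was that at the insertion positions, and the next longest held 2 windows. Counting every change to an earlier fraction, 5 runs held at least 4 windows and the longest held 6. Of the 3845 other windows of 100 kb, 2 were as high as the insertion positions in both the weighted average and the share-based index, and both lay within 500 kb of a stretch end. This joint count and the counts of leading fractions were also chosen after the data had been seen.

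By the share-based index, the largest run of differences on chromosome 1 outside the target region was towards later replication. It lay at 149650001 to 149850000, a region chosen after its values were seen, where the index was 2.61 in Wt and 1.69 in the clone. Its summed signal was at the 1.67th percentile of windows. Of the 90 windows whose leading fraction changed from S1 to S4 or back, 33 lay in the lowest 10% of summed signal, and their median was at the 12.7th percentile.

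The first pattern was the earlier replication at the insertion positions. More total signal without a change in its distribution over S phase would leave the share-based index in place, but the index rose by 2.77 SD of other 100 kb windows, which argues against total signal as the whole cause. The argument is weaker with S4 left out, where the rise was 0.55 and the SD of other windows 0.353. With S1, S2 or S3 left out in turn, the rise was 0.648 or more and the SD 0.231 or less. The spread between the libraries of a mid-replicating interval was weighed by the share of windows of similar Wt index that rose as far, 1.09% (11 of 1006). This share is above the 1% set as the limit, and although 0 of 535 windows of the same stretch rose as far, windows are not replicate libraries, so the shift and the spread between single libraries cannot be told apart. An effect of the inserted modules, the difference the design names, stays open, as does a difference between this clone and other clones, and neither can be tested with 1 library per fraction.

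The second pattern was the rise of the weighted average by 1.08 from 72950001 to 73050000, in the part of the target region that was led by S1 in both lines. The share-based index moved there by 0.192 SD of other windows while the summed signal was 26.3% higher. These values go with more signal in an interval that was already early. They cannot exclude a shift to earlier fractions, since an index in a part led by S1 has little room to rise. The SD was also taken over windows of all timings. The deposited values differed by 0.522 in S1 and 0.462 in S2, against -0.0276 in S3 and 0.027 in S4. A candidate explanation for the higher signal was not tested, and no biological explanation was tested.

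The third pattern was the set of large differences elsewhere on chromosome 1. Windows within 500 kb of a stretch end made up 48.7% of the top 1% and 8.50% of all windows, a 5.73-fold excess, so part of these differences may come from the ends of the stretches in which the authors' values are scaled. The runs at 48100001 to 48200000, 1904 kb from an end, and at 195550001 to 195600000, 577 kb from an end, are not covered by this explanation. Scaling within stretches does not act on the fraction profiles, which are scaled over the chromosome. In them S1 was 2.57 in Wt and 6.18 in the clone at 194350001 to 194400000, and 3.96 and 7.60 at 194200001 to 194250000. These differences in S1 do not come from that scaling. At 100400001 to 100550000, also near an end, S1 was close in both lines (-0.628 and -0.594). Total signal is also open. Over all windows the difference in the weighted average had an r of 0.783 with that in summed signal (0.147 for the index). Both had the same sign in 38 of the top 39 windows, which were picked by the weighted average. In the fit for Wt around the target region, the weighted average rose with each fraction, as the summed signal does. These values therefore follow in large part by construction and cannot decide this explanation. In 29 of the 39 (74.4%) the index moved by less than 1 SD of other windows, just under the 75% set for this explanation, and no biological explanation was tested.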
